A study of Canis lupus familiaris with 18 samples.

How the data were processed

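The series measured gene expression in subcutaneous and gonadal fat of 9 intact female beagles, 4 years old, with Affymetrix canine arrays. After randomisation 4 control dogs were fed to hold their starting body weight and stayed lean, and 5 dogs were fed ad libitum and became obese, for 24 weeks. Both depots of each dog were sampled after an overnight fast, which gives 18 arrays in 4 depot-by-feeding groups. Per the labels, total RNA was taken with Trizol and labelled with biotin as cRNA by a one-cycle protocol. The pairing of depots rests on the animal number in the labels. The labels give the subcutaneous arrays, and not the gonadal ones, as part of an earlier submission with other processed values, so depot and any array batch cannot be told apart. Scan dates are not given in the sources used here.

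The deposited table holds expression values, read here as log2, that were computed by GCRMA per the submitters' processing notes, 1 column per array. The base of the logarithm and the GCRMA version and options are not given in the sources used here. The values, 0.68 to 16.51 with array medians of 3.65 to 3.87, lie in the range of log2 signals. Scanner files and detection calls were not used here. A probe set is a group of short probes on the array for 1 transcript. Of 43035 probe sets 111 were array controls. The platform annotation gave 1 gene symbol to 29254 of the other 42924, several to 439, and listed none for 13231. No 2 arrays were identical, and every column matched a sample.

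Probe sets with a log2 value of at least 4 in at least 4 of the 18 arrays were tested, 21484 in all, of which 16062 carry 1 symbol. Log2 4 is the floor named in the report. In each array 47.2% to 49.0% of probe sets lay at or above it, and where the mean of a group lies below it the difference of a gene that passed is given as a bound, with that mean set to the floor. R 4.3.3 with limma 3.58.1 and statmod 1.5.0 fitted the 4 group means over all 18 arrays with no block for the dog, and moderated the spread (14 residual degrees of freedom, 2.54 added by moderation). The 5 comparisons were ad libitum minus control in each depot (5 dogs against 4), gonadal minus subcutaneous in each feeding group (4 and 5 dogs), and the difference between the feeding responses of the depots. Tests are two-sided, with Benjamini-Hochberg adjustment over the probe sets of a comparison and a threshold of 0.05. Errors printed after ± are standard errors from limma unless SD is given.

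A gene is represented by its probe set with the highest mean, which gives 8656 genes. The genes named were set by a rule written before the data were examined. It takes, per comparison, the 10 largest increases and the 10 largest decreases among genes past the threshold, for depots only genes that moved the same way in every dog. Where under 10 genes passed it adds the 5 smallest p values. It also takes up to 4 members of a list with the smallest p, and LEP, ADIPOQ, CCL2, TNF and IL6 for feeding. The markers of ciliated epithelium and of the oviduct were chosen after the arrays that carry them were seen. The 28 gene lists, on metabolism, cell types, tissues and stress, were fixed before the files were seen. The 22 with at least 5 measured members were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. Of the lists called by camera, 0 of 8 held with an estimated correlation for feeding in subcutaneous fat, and 1 of 3 in gonadal fat. For depot the numbers were 1 of 9 in control dogs and 1 of 8 in ad libitum dogs, and 0 of 7 for the interaction. By fry 0, 1, 6, 4 and 0 lists were called. It tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes.

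The fit was tested on simulated data with this design and 200 changed probe sets of 21484. The noise was drawn independently for each probe set and array, with the spread of that probe set. It had no effect of the dog, no correlation among genes and no outlying arrays, so recovery in the real arrays may differ. Of changes of 2 log2 units 84% were recovered for feeding in subcutaneous fat, 79% in gonadal fat, 74% and 89% for depot in control and ad libitum dogs, and 59% for the interaction. Of changes of 1 log2 unit 34%, 43%, 41%, 49% and 18% were recovered. False calls numbered 12 of 130, 8 of 130, 5 of 120, 7 of 145 and 3 of 80. RNA length was read from the actin 3' minus 5' signal and compared by exact permutation over 126 regroupings. The GAPDH 3' minus 5' signal averaged 2.52 and 2.51 in subcutaneous control and ad libitum arrays and 2.32 and 2.40 in gonadal ones, and the hybridisation controls 11.26, 11.15, 11.33 and 11.29.

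The alternatives written before the data were examined were no filter and a filter at log2 6 (16450 probe sets), quantile normalization again and centring each array on its median, and a trended and robust moderation. Others were a fit to only the arrays of a comparison, the dog as a random or fixed block, 1 probe set per gene, a threshold of 0.1, a 1.5-fold minimum, and leaving out each dog with both arrays. Chosen after seeing the data were a fit without the 2 arrays that carry ciliated-cell transcripts, a fit without the 4 arrays that carry most of the muscle or ciliated-cell transcripts, a fit that also leaves out subcutaneous ad libitum dog 7, and the actin signal as a covariate. The fit without 4 arrays keeps dogs 1 and 9 alone as subcutaneous controls, and dogs 5, 7 and 8 in the gonadal ad libitum group. A threshold missed in it can therefore come from fewer arrays, and does not by itself show that a call rested on other tissues. Labels were also regrouped, in all 35 ways of halving the 8 arrays of the control dogs and in 100 splits for each other comparison. The sign of the feeding difference in both depots was compared over all 126 regroupings of the dogs, also chosen after seeing the data. With the dog as a random block the correlation between the depots of a dog was 0.168. The random seed was 20240. Genome positions were not analysed here.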

Results

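With ad libitum feeding 4 genes of fat storage and fatty acid synthesis, LEP, PNPLA3, ELOVL6 and DGAT2, were higher in subcutaneous fat (5 ad libitum dogs against 4 control dogs). LEP, the adipocyte hormone that signals fat mass, rose by 2.71 ± 0.67 on the log2 scale (log2 difference ± standard error, adjusted p = 0.0468), from a mean of 8.96 ± 1.13 (SD) to 11.67 ± 0.74. PNPLA3, a lipid droplet protein, rose by 4.41 ± 0.89 (adjusted p = 0.0245), and ELOVL6, which lengthens fatty acids, by at least 9.42-fold (adjusted p = 0.0248), a bound, because its control mean lay below the floor of log2 4. DGAT2, which makes triglyceride, rose by 2.35 ± 0.56 (adjusted p = 0.041). CDO1, cysteine dioxygenase, fell by 3.10 ± 0.55 on the log2 scale (adjusted p = 0.0183). ADIPOQ differed by 0.40 ± 0.35 (adjusted p = 0.497) and the chemokine gene CCL2 by -0.30 ± 0.65 (adjusted p = 0.809), and neither passed. In the fit without the 4 arrays that carry muscle or ciliated-cell transcripts LEP stood at 2.40 (adjusted p = 0.208), PNPLA3 at 3.57 (adjusted p = 0.167), and CDO1 at -3.68 (adjusted p = 0.0853), and ELOVL6 had an adjusted p = 0.113. That fit kept only dogs 1 and 9 as subcutaneous controls, so a missed threshold there can come from fewer arrays.

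FAM83A rose at least 12.8-fold in subcutaneous fat (adjusted p = 0.0236) and lay below the floor in all 4 control arrays. FITM2, which takes part in lipid droplet formation, rose at least 4.84-fold (adjusted p = 0.0422). NPR3, the clearance receptor for natriuretic peptides, rose by 3.34 ± 0.69 (adjusted p = 0.0251). LOX, which crosslinks collagen and elastin, rose by 3.29 ± 0.66 (adjusted p = 0.0245), and the adhesion receptor ADGRG4 by at least 6.37-fold (adjusted p = 0.0163). NNAT rose by 3.18 ± 0.56 (adjusted p = 0.0181) and the stress-induced gene GADD45G by 2.88 ± 0.58 (adjusted p = 0.0245). Lower with ad libitum feeding were the chemokine CCL19 (at least 4.17-fold, adjusted p = 0.0428) and the secreted glutathione peroxidase GPX3 (-1.82 ± 0.46, adjusted p = 0.0491). So were the matrix genes ISLR (-1.70 ± 0.43, adjusted p = 0.0498) and FBLN1 (-1.52 ± 0.39, adjusted p = 0.0496), and SOCS2, an inhibitor of cytokine and growth hormone signalling (-1.39 ± 0.28, adjusted p = 0.0245). IER5L (-1.50 ± 0.33, adjusted p = 0.0323), ANKRD37 (-1.38 ± 0.34, adjusted p = 0.044) and ILDR2 (-1.30 ± 0.25, adjusted p = 0.0236) also fell. MYOM1, a sarcomere gene, fell by 2.82 ± 0.69 on the log2 scale (adjusted p = 0.0447). In 2 of the 4 control arrays there were skeletal muscle transcripts, with muscle markers 7.09 (dog 3) and 5.65 (dog 4) log2 units above the other subcutaneous arrays at the median.

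**Figure D1:**
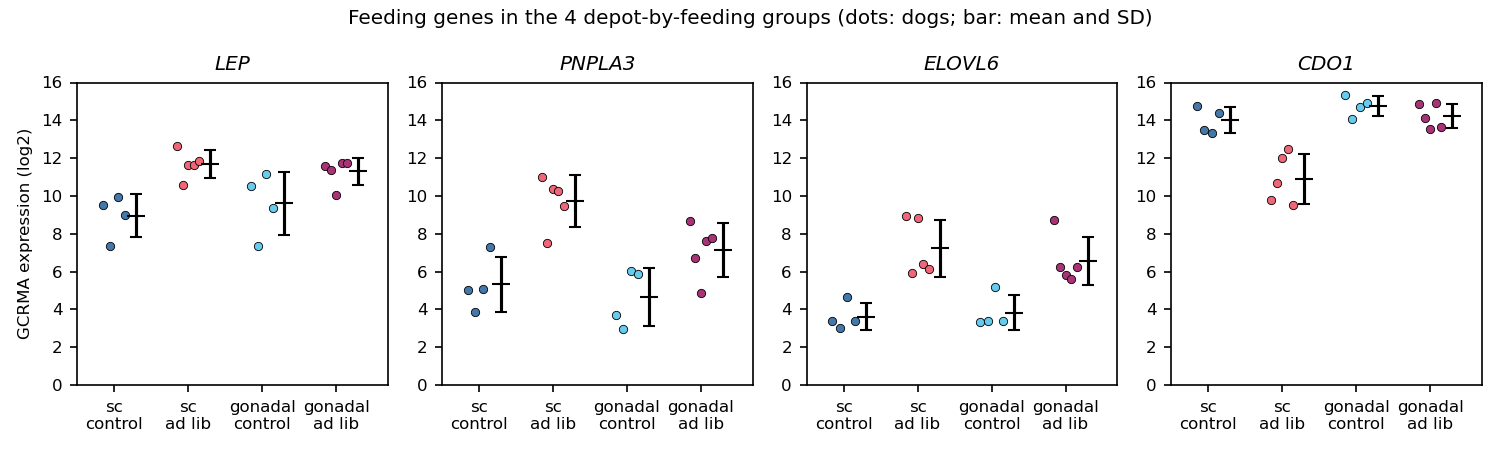
Each point is 1 array of 1 dog (control 4 dogs, ad libitum 5 dogs, sc = subcutaneous), the vertical axis is the GCRMA value in log2 units, and the bars give the mean and SD of each depot-by-feeding group for LEP, PNPLA3, ELOVL6 and CDO1. LEP in subcutaneous fat has a mean of 8.96 in control dogs and 11.67 in ad libitum dogs, and in gonadal fat 9.61 and 11.30.

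In subcutaneous fat 506 of 21484 probe sets passed (409 higher, 97 lower, limma, adjusted p under 0.05). At 1 probe set per gene that is 200 of 8656 genes, 170 higher and 30 lower. Leaving out dog 1, 8, 4, 7, 2, 9 or 3 in turn gave 3, 10, 11, 16, 25, 77 and 98 probe sets, and leaving out dog 5 gave 2703. A fit without the 4 arrays that carry muscle or ciliated-cell transcripts gave 5 (1 higher, 4 lower), of which 3 are among the 506, and all 506 kept their sign. It shares most arrays with the fit that chose the 506, so a kept sign was likely from the start. It kept only dogs 1 and 9 as subcutaneous controls, so the drop in calls can come from fewer arrays. With the array's actin 3' minus 5' signal as a covariate 1 passed.

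Of 21 measured genes of adipocyte identity and lipid storage, 3 rose and none fell, or 5 rose adjusted over the list alone (mean difference 1.02, camera adjusted p = 0.000949). The 3 are LEP, DGAT2 and ACSL1, which activates fatty acids (1.67 ± 0.36, adjusted p = 0.0293). GPAM, with a control mean below the floor, missed the threshold at 3.57 ± 0.91 (adjusted p = 0.0502). Of 15 genes on the list of de novo lipogenesis, called fatty acid synthesis here, 3 rose (5 adjusted over the list alone, mean 1.02, camera adjusted p = 0.00175). They are ELOVL6, the transketolase TKT (1.28 ± 0.30, adjusted p = 0.0383) and PCK1, which feeds glycerol synthesis in fat cells (2.36 ± 0.52, adjusted p = 0.0323). The list is thus wider than the enzymes that make fatty acids. ME1 missed at 1.10 ± 0.30 (adjusted p = 0.0615). Of 12 genes of cholesterol synthesis 1 rose, CYP51A1 (1.45 ± 0.35, adjusted p = 0.0423), or 4 adjusted over the list alone (mean 0.74, camera adjusted p = 0.00415). Of 17 genes of lipolysis and fatty acid oxidation 1 rose, the mitochondrial transferase CPT2 (0.73 ± 0.18, adjusted p = 0.047), or 7 adjusted over the list alone (mean 0.64, camera adjusted p = 0.00394). The hormone-sensitive lipase LIPE stood at 1.80 ± 0.63 (adjusted p = 0.113). All 21 measured genes of oxidative phosphorylation had a positive difference and none passed (mean 0.44, camera adjusted p = 4.13e-05). NDUFA4 stood at 0.75 ± 0.21 (adjusted p = 0.0708). With an estimated correlation in place of the preset 0.01 each of these lists had an adjusted p = 0.651. Without the 4 arrays that carry muscle or ciliated-cell transcripts adipocyte identity (mean 0.70, camera adjusted p = 0.0305), fatty acid synthesis (0.63, 0.0408) and lipolysis (0.51, 0.0305) were still called. Each had an adjusted p = 0.894 there with an estimated correlation. With the array of ad libitum dog 7 left out as well, adipocyte identity had a mean of 0.60 (camera adjusted p = 0.0654), fatty acid synthesis 0.61 (0.0582) and lipolysis 0.47 (0.0533), and these 3 were not called. Cholesterol synthesis (mean 0.67, camera adjusted p = 0.0341) and oxidative phosphorylation (mean 0.42, 6.74e-05) were still called there.

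Complement genes lay lower as a list in subcutaneous fat (14 measured, none passed, 4 fell adjusted over the list alone, mean -0.58, camera adjusted p = 0.00898, adjusted p = 0.651 with an estimated correlation). C1R stood at -1.39 ± 0.39 (adjusted p = 0.0642) and C3 at -1.37 ± 0.48 (adjusted p = 0.114). Of 27 matrix genes LOX rose and the others did not pass. The list had a mean of -0.32 (camera adjusted p = 0.0193, adjusted p = 0.75 with an estimated correlation), and of -0.18 (camera adjusted p = 0.232) without the 4 arrays that carry muscle or ciliated-cell transcripts. None of 13 skeletal muscle genes passed (mean -2.53, camera adjusted p = 0.00415, adjusted p = 0.651 with an estimated correlation). MYLPF, a fast muscle light chain with an ad libitum mean below the floor, stood at -3.92 ± 1.80 (adjusted p = 0.199) and MYH2 at -4.20 ± 2.15 (adjusted p = 0.243). Leaving out the 4 arrays with muscle or ciliated-cell transcripts, the mean of that list was 0.41, MYLPF stood at 0.30 and MYH2 at 0.58. The array of ad libitum dog 7 has a lower level of muscle transcripts, and with it left out as well the list mean was 0.09.

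Macrophage markers were not called for feeding in subcutaneous fat (20 measured, none passed, mean 0.18, camera adjusted p = 0.933). The scavenger receptor MSR1 stood at 1.99 ± 0.52 (adjusted p = 0.0534). In the array of ad libitum dog 5 the macrophage score, 2.22, was the highest of the subcutaneous arrays, and its adipocyte list score was -0.99. Of 15 genes of inflammation 1 fell, NFKB1 (-0.85 ± 0.21, adjusted p = 0.0468, list camera adjusted p = 0.722). Neither TNF nor IL6 was tested. All 3 TNF probe sets lay below the floor in all 18 arrays, and IL6 reached it in 2. Of 16 genes of the unfolded protein response 1 rose, ASNS, asparagine synthetase (1.63 ± 0.40, adjusted p = 0.0447, list camera adjusted p = 0.27). The actin 3' minus 5' signal, which grows as RNA shortens, averaged 4.75 ± 1.02 (SD) in subcutaneous control arrays and 3.49 ± 0.77 in ad libitum ones (difference -1.27, exact permutation p = 0.0873, two-sided, 126 regroupings).

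No probe set passed for feeding in gonadal fat (0 of 21484, limma, 531 with unadjusted p under 0.05, smallest adjusted p = 0.99994), with 5 ad libitum dogs against 4 control dogs. LEP stood at 1.69 ± 0.67, ELOVL6 at 2.71 ± 0.74 (control mean below the floor), ADIPOQ at 0.03 ± 0.35 and CCL2 at 0.05 ± 0.65. The number with unadjusted p under 0.05 was 1277 without the 2 arrays that carry ciliated-cell transcripts, of which gonadal dog 6 belongs to this comparison, and 1304 without the 4 arrays that carry muscle or ciliated-cell transcripts, again with 0 passing. The smallest unadjusted p values belonged to FAM20A (2.02 ± 0.39, control mean below the floor), the protease SPPL2A (0.88 ± 0.21), AADAT (-1.03 ± 0.26), EPDR1 (1.12 ± 0.29) and YEATS2 (0.69 ± 0.18), all with adjusted p = 0.99994. On simulated data with this design 79% of genes changed by 2 log2 units in gonadal fat were recovered, and 43% of those changed by 1. The simulated noise was independent and held no outlying arrays, unlike the real gonadal arrays, so these shares do not give the power reached here.

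Homeobox and other positional genes lay lower as a list in gonadal fat of ad libitum dogs (18 measured, none passed, mean -0.34, camera adjusted p = 0.00126, adjusted p = 0.0145 with an estimated correlation). GATA6 stood at -0.79 ± 0.32 and HOXB7 at -0.50 ± 0.26. Leaving out the 4 arrays with muscle or ciliated-cell transcripts, this list had a camera adjusted p = 0.115. Immediate early genes of the stress of sampling had a mean of -0.40 (16 measured, none passed, camera adjusted p = 0.0105, adjusted p = 0.972 with an estimated correlation). FOS stood at -1.37 ± 0.69 and JUN at -0.99 ± 0.48, and the list had a camera adjusted p = 0.231 in that fit without 4 arrays. Genes of fatty acid synthesis had a mean of 0.36 (15 measured, none passed, 1 rose adjusted over the list alone, camera adjusted p = 0.0347, adjusted p = 0.972 with an estimated correlation, camera adjusted p = 0.211 in that fit). In the same fit adipocyte identity (mean 0.52) and endothelium (mean 0.42) were called for feeding in gonadal fat (both camera adjusted p = 0.00859, adjusted p = 0.814 with an estimated correlation). The actin 3' minus 5' signal averaged 2.91 ± 0.91 (SD) in gonadal control arrays and 3.31 ± 0.91 in ad libitum ones (difference 0.40, exact permutation p = 0.532, two-sided).

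Of the 506 probe sets called for feeding in subcutaneous fat 439 had the same sign in gonadal fat, against a median of 343 among the 506 with the smallest p in the other regroupings of the dogs, both depots of a dog moved together. These ranged from 149 to 465, and at least as many were reached in 5 of 126 regroupings, the real one included. Both depots come from the same dogs, so the shared sign is not independent evidence of a feeding response. In gonadal fat the median difference of the 409 higher ones was 0.24 against 1.25, and that of the 97 lower ones -0.23 against -1.11. Of the 506, 365 had an unadjusted interaction p under 0.05, a share raised by their choice on the subcutaneous difference. No probe set passed the test of whether the feeding difference depends on the depot (0 of 21484, limma, 1344 with unadjusted p under 0.05, smallest adjusted p = 0.254). For no single gene is the feeding response therefore shown to differ between the depots. The smallest unadjusted p values among genes were those of the kinase CDK12 (1.28 ± 0.23, adjusted p = 0.309) and KIAA0930 (-1.68 ± 0.34, adjusted p = 0.456), as gonadal minus subcutaneous response in 9 dogs. Next came the complement subunit C8G, given without a size because its mean lay below the floor in 3 of the 4 groups, and MARK1 (-1.92 ± 0.41), both with adjusted p = 0.456, and VRK2 (-1.39 ± 0.32, adjusted p = 0.67). PCK1 stood at -1.98 ± 0.74 and ACSL1 at -1.15 ± 0.51 (both adjusted p = 0.748). This test is the weakest of the design, with 59% of simulated effects of 2 log2 units recovered. Leaving out dog 5, 6 or 8 gave 5, 2 and 1 probe sets.

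As lists, 7 sets of genes had a feeding response that depended on the depot by camera, and none with an estimated correlation. Oxidative phosphorylation had a mean of -0.45 (camera adjusted p = 1.01e-05), adipocyte identity -0.75 and lipolysis and fatty acid oxidation -0.51 (both camera adjusted p = 0.0101). Fatty acid synthesis stood at -0.66 and cholesterol synthesis at -0.48 (both camera adjusted p = 0.0427), each with the smaller response in gonadal fat. In the fit without the 4 arrays that carry muscle or ciliated-cell transcripts adipocyte identity was at -0.18 (camera adjusted p = 0.711), fatty acid synthesis and lipolysis had a camera adjusted p = 0.192 and cholesterol synthesis 0.0636, and oxidative phosphorylation kept its call (mean -0.53, camera adjusted p = 2.43e-08, adjusted p = 0.78 with an estimated correlation). Complement stood at 0.57 (camera adjusted p = 0.0101) and skeletal muscle at 3.68 (camera adjusted p = 6.46e-05). Adipocyte identity and fatty acid synthesis had an adjusted p = 0.796 with an estimated correlation, and the other 5 lists an adjusted p = 0.794. The skeletal muscle mean was -0.70 in that fit. With the dog as a fixed block mesothelium markers were also called (mean 0.89, camera adjusted p = 0.0331, against 0.103 without the block), with an adjusted p = 0.618 under the block and an estimated correlation.

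In control dogs GATA6, C3, C6 and ALDH1A2 were higher in gonadal than in subcutaneous fat, and PI3, MMP2 and COL1A1 were lower (4 dogs, both depots). GATA6, a transcription factor of visceral mesoderm, was higher in gonadal fat by at least 4.93-fold (adjusted p = 0.00111). The complement gene C3 was higher by 2.54 ± 0.50 on the log2 scale (adjusted p = 0.0132), and C6 by 3.80 ± 0.69 (adjusted p = 0.00865). ALDH1A2, which makes retinoic acid, was higher by at least 6.89-fold (adjusted p = 0.0229). PI3, the protease inhibitor elafin, was lower by 6.59 ± 0.54 on the log2 scale (adjusted p = 1.21e-05). The matrix protease MMP2 was lower by 3.85 ± 0.64 (adjusted p = 0.00432) and the collagen gene COL1A1 by 2.17 ± 0.41 (adjusted p = 0.0116). In the fit without the 4 arrays that carry muscle or ciliated-cell transcripts ALDH1A2 (adjusted p = 0.0665), MMP2 (0.0653) and COL1A1 (0.116) missed the threshold, and the other 4 of these genes passed. There the subcutaneous controls were dogs 1 and 9 alone, so a missed threshold can come from fewer arrays. The labels give the subcutaneous arrays alone as part of an earlier submission, so depot and any array batch cannot be told apart in these differences.

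Further genes higher in gonadal fat of control dogs were PRR15 (at least 38.2-fold, adjusted p = 0.00195), UPK1B (at least 9.33-fold, adjusted p = 0.00292), the growth factor FGF9 (at least 7.02-fold, adjusted p = 0.00489) and the homeobox gene ALX1 (at least 9.56-fold, adjusted p = 0.000774). Of the 4 subcutaneous control arrays 3 lay below the floor for each of these 4 genes, and the fourth, of dog 4, is the one with ciliated-cell transcripts. GPM6A (3.51 ± 0.89, adjusted p = 0.0454), the Wnt inhibitor WIF1 (3.17 ± 0.65, adjusted p = 0.0156), PDE8B (3.14 ± 0.45, adjusted p = 0.00136) and the glutamate transporter SLC1A1 (at least 5.14-fold, adjusted p = 0.00423) were also higher. Lower were TMEFF2 (-6.02 ± 0.60, adjusted p = 0.000105), the matrix gene VIT (at least 40.2-fold, adjusted p = 3.67e-05) and the Wnt inhibitor SFRP4 (-5.16 ± 1.01, adjusted p = 0.0122). GPNMB, a gene of lipid-laden macrophages, was lower by 4.94 ± 1.06 on the log2 scale (adjusted p = 0.0212, and 0.0529 with the dog as a fixed block). CILP (-4.60 ± 0.67, adjusted p = 0.00176), DPP4 (-4.54 ± 0.87, adjusted p = 0.0116), FNDC1 (-4.36 ± 0.58, adjusted p = 0.00104) and PI16 (-4.19 ± 0.55, adjusted p = 0.00103) were lower, and so was the protease MMP27 (at least 4.59-fold, adjusted p = 0.0116). DPP4 and PI16 mark adipose progenitor cells. In the fit without 4 arrays GPM6A (adjusted p = 0.106), GPNMB (0.12), DPP4 (0.11) and MMP27 (0.136) missed the threshold.

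In control dogs 627 of 21484 probe sets passed for depot (236 higher and 391 lower in gonadal fat, 4 dogs), or 255 genes, 99 higher and 156 lower. With the dog as a random block 1346 passed (575 higher, 771 lower). The actin 3' minus 5' signal averaged 4.75 ± 1.02 (SD) in subcutaneous and 2.91 ± 0.91 in gonadal control arrays, and with it as a covariate 199 passed (54 higher, 145 lower). Without the 4 arrays that carry muscle or ciliated-cell transcripts 341 passed, 171 higher and 170 lower, so the excess of lower calls was not seen there. Nor was it clear without dog 3 (70 higher, 73 lower) or dog 9 (262 higher, 244 lower), and dog 9 has none of the 4 arrays. It stayed when any other dog was left out, such as dog 4 (74 higher, 204 lower). It also stayed without the 2 arrays that carry ciliated-cell transcripts (337 higher, 541 lower). The 4 arrays are thus not shown to be its source. Leaving out dog 1, 3, 4, 7 or 8 gave 149, 143, 278, 350 and 322, and leaving out dog 6 gave 1050.

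**Figure D2:**
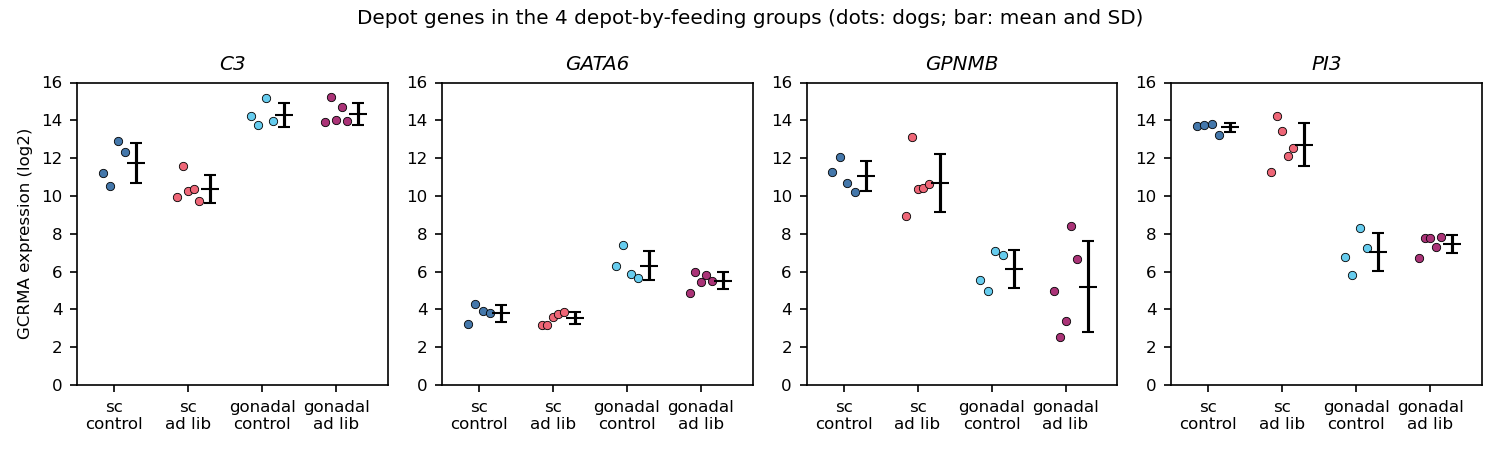
Each point is 1 array of 1 dog (control 4 dogs, ad libitum 5 dogs, sc = subcutaneous), the vertical axis is the GCRMA value in log2 units, and the bars give the mean and SD of each depot-by-feeding group for C3, GATA6, GPNMB and PI3. C3 has gonadal means of 14.28 and 14.35 against subcutaneous means of 11.74 and 10.37 (control and ad libitum), and PI3 has 7.03 and 7.48 against 13.62 and 12.71.

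Of 18 positional genes 4 were higher in gonadal fat of control dogs and none lower (7 higher adjusted over the list alone, mean 0.82, camera adjusted p = 0.00013). The list had an adjusted p = 0.00952 with an estimated correlation, and 0.102 with that and the dog as a fixed block. These were GATA6, TCF21 (at least 1.9-fold, adjusted p = 0.0102), HOXB7 (1.27 ± 0.28, adjusted p = 0.0236) and HOXA5 (1.00 ± 0.22, adjusted p = 0.0237). Of 12 mesothelium markers 5 were higher and 1, the keratin KRT7, lower (-3.16 ± 0.79, adjusted p = 0.0428, and 0.125 without the 4 arrays that carry muscle or ciliated-cell transcripts). RSPO1 (at least 2.52-fold, adjusted p = 0.0115) and PKHD1L1 (3.04 ± 0.71, adjusted p = 0.0316) are among the 5. Adjusted over the list alone 8 were higher and 1 lower (mean 2.06, camera adjusted p = 1.86e-05, adjusted p = 0.249 with an estimated correlation). When the 4 arrays with muscle or ciliated-cell transcripts were left out 7 were higher and none lower, with an adjusted p = 0.0149 under an estimated correlation. Of 14 complement genes C3 and C6 were higher and none lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.287).

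Of 27 matrix genes 6 were lower in gonadal fat of control dogs and none higher (14 lower adjusted over the list alone, mean -1.09, camera adjusted p = 4.93e-07). They include FBN1 (-1.98 ± 0.40, adjusted p = 0.0139) and COL6A1 (-1.91 ± 0.42, adjusted p = 0.0229). Of 20 macrophage markers 3 were lower and none higher (9 lower adjusted over the list alone, mean -1.25, camera adjusted p = 1.03e-07). They include CD83 (-2.21 ± 0.39, adjusted p = 0.00673) and the cathepsin gene CTSS (-1.30 ± 0.30, adjusted p = 0.0302), and MRC1 missed the threshold at -1.84 ± 0.48 (adjusted p = 0.0504, and 0.0405 with the dog as a fixed block). Of 16 genes of the unfolded protein response 2 were lower (5 adjusted over the list alone, mean -0.35, camera adjusted p = 0.0022). They are DDIT3 (-1.62 ± 0.33, adjusted p = 0.0153) and SDF2L1 (-1.28 ± 0.31, adjusted p = 0.0348). Smooth muscle and pericyte markers had a mean of 1.44 (11 measured, none passed, 4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00236). RGS5 stood at 2.16 ± 0.60 (adjusted p = 0.0597, and 0.0411 with the dog as a fixed block). These 4 lists had an adjusted p = 0.249 with an estimated correlation. In the fit without 4 arrays COL6A1 (adjusted p = 0.15), CTSS (0.106), DDIT3 (0.111) and SDF2L1 (0.0544) missed the threshold.

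Inflammatory genes had a mean of -0.78 for depot in control dogs (15 measured, none passed, 1 lower adjusted over the list alone, camera adjusted p = 0.00203, adjusted p = 0.408 with an estimated correlation). CCL2 stood at -1.79 ± 0.68 (adjusted p = 0.154). Adipocyte genes had a mean of 0.58 (21 measured, none passed, camera adjusted p = 0.0155, adjusted p = 0.869 with an estimated correlation), and of 0.25 (camera adjusted p = 0.465) without the 4 arrays that carry muscle or ciliated-cell transcripts. Skeletal muscle genes had a mean of -2.91 (13 measured, none passed, 1 lower adjusted over the list alone, camera adjusted p = 0.00256, adjusted p = 0.682 with an estimated correlation). MYBPC1 stood at -5.03 ± 1.35 (adjusted p = 0.0548, and 0.0451 with the dog as a fixed block) and MYLPF, with a gonadal mean below the floor, at -4.16 ± 1.90 (adjusted p = 0.23). That mean was 0.031, and MYLPF stood at 0.060, in that fit. With the dog as a fixed block the lists of lipolysis and fatty acid oxidation (camera adjusted p = 0.0332, against 0.0528) and oxidative phosphorylation (0.0356, against 0.107) were also called, each with an adjusted p = 0.76 under the block and an estimated correlation. Among single list members, the circadian gene PER3 was higher in gonadal fat (1.13 ± 0.27, adjusted p = 0.0369, and 0.065 with the dog as a fixed block). The acyl-CoA dehydrogenase ACADL was higher (1.17 ± 0.31, adjusted p = 0.0494) and the kinase GSK3B lower (-0.84 ± 0.20, adjusted p = 0.0328). PER3 (adjusted p = 0.17), ACADL (0.237) and GSK3B (0.0946) missed the threshold without the 4 arrays.

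In ad libitum dogs the largest increases in gonadal over subcutaneous fat included the epithelial genes EPCAM, KRT18 and KRT8 (5 dogs, both depots). The epithelial adhesion gene EPCAM was higher by at least 178-fold (adjusted p = 0.00318). The keratins were higher as well, KRT18 by at least 87.9-fold (adjusted p = 0.00247) and KRT8 by 4.70 ± 1.05 on the log2 scale (adjusted p = 0.0142), and UPK1B by at least 10.7-fold (adjusted p = 9.74e-05). In the gonadal array of dog 6 markers of ciliated epithelium lay 4.82 log2 units above the other gonadal arrays at the median, and EPCAM reached 14.01. EPCAM (adjusted p = 4.95e-08), KRT18 (3.81e-06) and KRT8 (3.92 ± 0.54, adjusted p = 0.00091) still passed without that array and subcutaneous control dog 4, so they do not rest on it alone. C3 was higher by 3.98 ± 0.45 (adjusted p = 9.90e-05) and GATA6 by at least 2.86-fold (adjusted p = 0.00119). PI3 was lower by 5.23 ± 0.48 on the log2 scale (adjusted p = 2.34e-05) and the matrix gene THBS4 by 4.75 ± 0.37 (adjusted p = 3.48e-06). The EPCAM difference was not particular to ad libitum dogs. Without gonadal ad libitum dog 6 and subcutaneous control dog 4 it passed in control dogs too (adjusted p = 2.10e-07). Subcutaneous control dog 4 stood at 12.91 for EPCAM, and the other subcutaneous control arrays at 3.20 to 3.40.

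Other genes higher in gonadal fat of ad libitum dogs were SCG5 (at least 26.1-fold, adjusted p = 0.00736), PRR15 (at least 23.5-fold, adjusted p = 0.000336), ECRG4 (at least 36.0-fold, adjusted p = 0.000275) and WIF1 (5.31 ± 0.58, adjusted p = 9.74e-05). GPM6A (4.84 ± 0.80, adjusted p = 0.00236), the tight junction gene CGN (at least 10.4-fold, adjusted p = 0.00969) and C6 (4.66 ± 0.62, adjusted p = 0.000438) were higher too. Lower were GPNMB (-5.50 ± 0.95, adjusted p = 0.00315), TMEFF2 (-5.27 ± 0.54, adjusted p = 6.53e-05), VIT (at least 31.5-fold, adjusted p = 1.43e-05) and CILP (-4.32 ± 0.60, adjusted p = 0.000614). BCL2A1, a survival gene of leukocytes, was lower (-4.06 ± 0.48, adjusted p = 0.000146), as was IGSF1 (at least 7.12-fold, adjusted p = 0.00508). ADGRG4 (adjusted p = 0.000106) and the protease MMP9 (adjusted p = 0.0245) were each lower by at least 6.37-fold.

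In ad libitum dogs 1545 of 21484 probe sets passed for depot (608 higher and 937 lower in gonadal fat, 5 dogs), or 645 genes, 234 higher and 411 lower. With each array centred on its median 1729 passed, 506 higher and 1223 lower. Without the 4 arrays that carry muscle or ciliated-cell transcripts 1623 passed, 801 higher and 822 lower, and 1118 (560 higher, 558 lower) with subcutaneous dog 7 also left out, so the excess of lower calls was not seen in those fits. With the dog as a random block 2495 passed (1048 higher, 1447 lower). Leaving out dog 5, 7 or 8 gave 842, 585 and 497. Between the depot differences of control and ad libitum dogs 101 probe sets were called higher in both and 192 lower in both. In opposite directions 0 were called. If the calls of both comparisons were independent, their counts would give 6.68 higher and 17.1 lower in both. They are not independent, since both comparisons use the same estimate of the spread of a probe set. Any array batch would also go with depot in both feeding groups. The overlap is therefore given with no test against chance. Of the 627 calls in control dogs 233 of the 236 higher and 389 of the 391 lower had the same sign in ad libitum dogs.

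Of 12 mesothelium markers 9 were higher in gonadal fat of ad libitum dogs and none lower (9 and 1 adjusted over the list alone, mean 2.95, camera adjusted p = 1.22e-07). The list had an adjusted p = 0.0766 with an estimated correlation, and 0.0303 with that and without the 4 arrays that carry muscle or ciliated-cell transcripts. PKHD1L1 is among the 9 (at least 10.2-fold, adjusted p = 0.00131). Of 18 positional genes 6 were higher and none lower (7 higher adjusted over the list alone, mean 0.66, camera adjusted p = 0.00115). This list had an adjusted p = 0.0283 with an estimated correlation, and 0.109 with that and the dog as a fixed block. They include TCF21 (at least 1.67-fold, adjusted p = 0.00394), HOXA5 (0.96 ± 0.20, adjusted p = 0.00875) and HOXB7 (1.14 ± 0.25, adjusted p = 0.0125). Of 14 complement genes C3 and C6 were higher (3 adjusted over the list alone, camera adjusted p = 0.525). The list's mean of 0.42 and median of -0.41 differ in sign. Smooth muscle and pericyte markers had a mean of 1.41 (11 measured, none passed, 5 higher adjusted over the list alone, camera adjusted p = 0.00336, adjusted p = 0.345 with an estimated correlation). TAGLN stood at 1.61 ± 0.48 (adjusted p = 0.0524, and 0.03 with the dog as a fixed block).

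Of 20 macrophage markers 5 were lower in gonadal fat of ad libitum dogs and none higher (12 lower adjusted over the list alone, mean -1.30, camera adjusted p = 5.14e-07, adjusted p = 0.474 with an estimated correlation). They include TREM2 (at least 1.53-fold, adjusted p = 0.0183), TYROBP (-1.62 ± 0.42, adjusted p = 0.0279) and CTSS (-0.99 ± 0.27, adjusted p = 0.0349). Of 27 matrix genes 5 were lower and none higher (10 lower adjusted over the list alone, mean -0.89, camera adjusted p = 0.000168, adjusted p = 0.544 with an estimated correlation). Among them are MMP2 (-3.19 ± 0.57, adjusted p = 0.00392), fibronectin FN1 (-1.87 ± 0.37, adjusted p = 0.00661) and COL1A1 (-1.56 ± 0.37, adjusted p = 0.0186). Inflammatory genes had a mean of -0.82 (15 measured, none passed, camera adjusted p = 0.0287, adjusted p = 0.769 with an estimated correlation), with a camera adjusted p = 0.065 without the 4 arrays that carry muscle or ciliated-cell transcripts. In that fit MMP9 (adjusted p = 0.063), COL1A1 (0.0636), TREM2 (0.0528), TYROBP (0.0561) and CTSS (0.133) missed the threshold.

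The malic enzyme ME1, which supplies reducing power for fatty acid synthesis, was lower in gonadal fat of ad libitum dogs by 1.48 ± 0.28 on the log2 scale (adjusted p = 0.00593), and CPT2 by 0.99 ± 0.17 (adjusted p = 0.00326). Of 21 genes of oxidative phosphorylation 1 was lower, NDUFS3 (-0.64 ± 0.18, adjusted p = 0.0418). NDUFS3 had an adjusted p = 0.0686 without the 2 arrays that carry ciliated-cell transcripts, and 0.0389 without the 4 arrays that carry muscle or ciliated-cell transcripts. Adjusted over the list alone 4 were lower (mean -0.27, camera adjusted p = 0.0117, adjusted p = 0.877 with an estimated correlation, camera adjusted p = 0.0735 without the 2 arrays that carry ciliated-cell transcripts). Without the 4 arrays that carry muscle or ciliated-cell transcripts the list was called (mean -0.38, camera adjusted p = 0.000927, adjusted p = 0.676 with an estimated correlation). Of 12 genes of cholesterol synthesis 1 was lower, MVD (-1.14 ± 0.29, adjusted p = 0.0249). Adjusted over the list alone 3 were lower (mean -0.49, camera adjusted p = 0.0476, adjusted p = 0.769 with an estimated correlation, camera adjusted p = 0.0983 without those 2 arrays). Without the 4 arrays the cholesterol list was called as well (mean -0.61, camera adjusted p = 0.0302, adjusted p = 0.676 with an estimated correlation). ASNS (-1.60 ± 0.37, adjusted p = 0.0173) and SDF2L1 (-1.07 ± 0.27, adjusted p = 0.0267) of the unfolded protein response were lower. IGFBP3, which binds insulin-like growth factors, was higher by 2.11 ± 0.39 (adjusted p = 0.00443). HK1, a hexokinase, was lower (-0.87 ± 0.24, adjusted p = 0.0394, 0.0633 with the dog as a fixed block, and 0.105 without the 4 arrays that carry muscle or ciliated-cell transcripts).

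Transcripts of other tissues were strongest in 4 of the 18 arrays. Of 28 detected markers of ciliated epithelium the median lay 2.68 log2 units above the other arrays of the depot in subcutaneous control dog 4 and 4.82 in gonadal ad libitum dog 6. In any other array it lay at most at 0.058. OVGP1, the oviduct-specific glycoprotein, stood at 9.94 and 11.31 in those 2 arrays, and EPCAM at 12.91 and 14.01. Skeletal muscle markers lay 7.09, 5.65 and 6.14 above the other arrays of the depot in subcutaneous control dog 3, subcutaneous control dog 4 and gonadal ad libitum dog 2. ACTA1, skeletal actin, stood there at 16.51, 15.68 and 16.24. Subcutaneous ad libitum dog 7 carried muscle transcripts at a lower level, with a median excess of 0.96 and 50% of the detected genes more than 1 log2 unit above the other subcutaneous arrays.

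**Figure D3:**
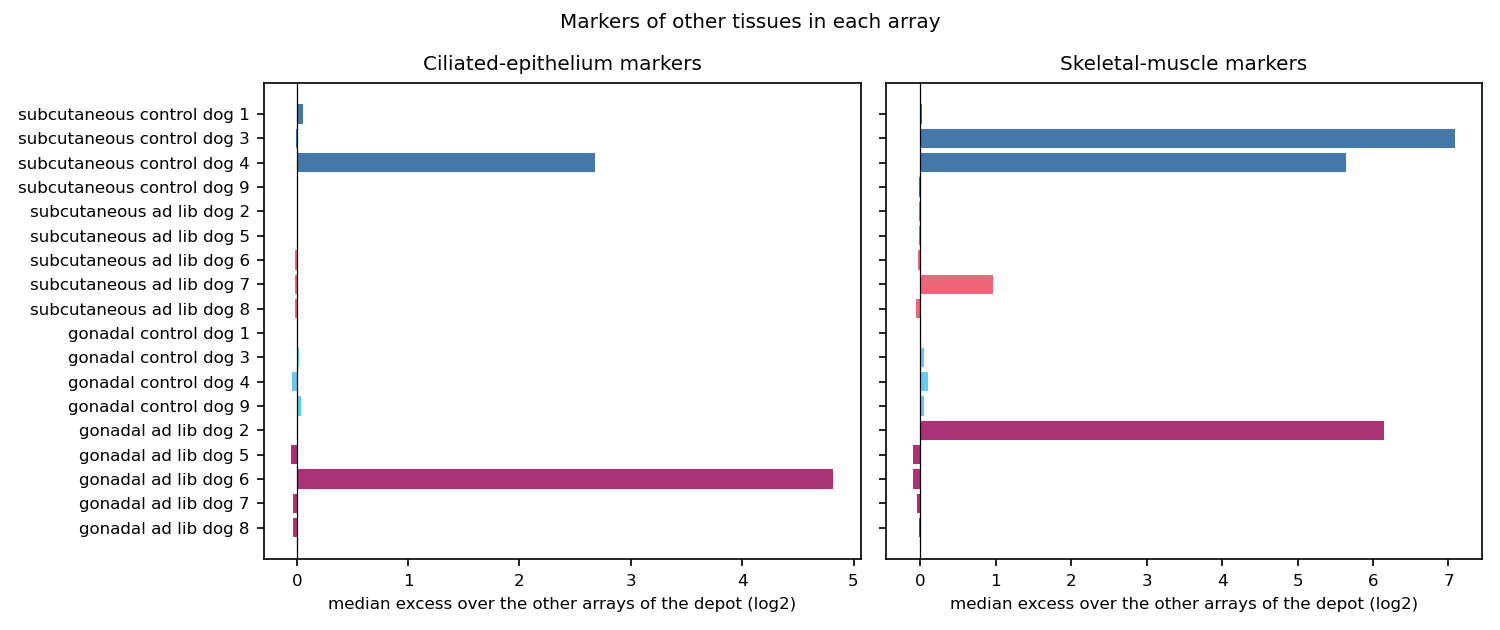
Each bar is 1 array, and its length on the horizontal axis is the median excess of a marker set over the other arrays of the same depot in log2 units, for ciliated epithelium and skeletal muscle. The ciliated set reaches 2.68 in subcutaneous control dog 4 and 4.82 in gonadal ad libitum dog 6, and the muscle set reaches 7.09, 5.65 and 6.14 in 3 arrays.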

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

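The tests for ciliated epithelium, for carry-over of RNA, for muscle fibres and for the label of subcutaneous ad libitum dog 5 were chosen after the result was seen, and the other tests here were written before. For the test of muscle and oviduct RNA as the source of the subcutaneous calls, the call counts without those arrays had been seen, and the median it measures had not.

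Of 319 pairs of a gene and a group 39 had 1 array apart from the rest of its group (12.2%), against 15.95 that chance gives at about 1 in 20 groups. In each of the 39 the gap to the nearest other array was at least 0.71 of the group's range, however small that range. Some lie below the floor, such as MMP27 in gonadal control dog 4 (1.91, the others 2.00 to 2.01). Pairs that share an array are not independent, so the number by chance is only a guide. Of the 39 the most, 8, fell on subcutaneous ad libitum dog 5. They were CCL19 5.75 (the others 2.94 to 3.64), ACSL1 12.32, GPAM 4.76, ADIPOQ 13.83, BCL2A1 12.22, PKHD1L1 4.42, MARK1 9.49 and S100B 9.34. In subcutaneous control dog 4 there were 7, all above the rest of the group. They were PRR15 7.04, UPK1B 5.57, FGF9 4.09, ALX1 5.09, ALDH1A2 4.12, RSPO1 3.05 and EPCAM 12.91. In subcutaneous ad libitum dog 2 there were 6, namely ISLR 3.47, SOCS2 6.08, MSMO1 9.76, ECRG4 5.91, HOXB7 6.44 and NDUFS3 12.68. Gonadal ad libitum dog 6 stood apart in LEP 10.06, ADIPOQ 14.09, MARK1 7.91 and PCK1 11.07, and gonadal control dog 4 in ELOVL6 5.19, FGF9 8.39, MMP27 1.91 and MYLPF 2.65. Subcutaneous ad libitum dog 7 stood apart in MYLPF 4.01, UPK1B 3.11 and MYH2 6.74, and gonadal ad libitum dog 2 in ELOVL6 8.75, IGSF1 4.25 and ASNS 9.80. Single cases were PRR15 4.12 in subcutaneous ad libitum dog 6, PI3 13.24 in subcutaneous control dog 9, PDGFRB 8.46 in subcutaneous control dog 1 and FOS 14.17 in gonadal control dog 9. The markers of ciliated epithelium, outside the comparisons, lay 2.68 above the other arrays of the depot in subcutaneous control dog 4 and 4.82 in gonadal ad libitum dog 6.

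Subcutaneous control dog 4 and gonadal ad libitum dog 6, of 2 different dogs, share transcripts of ciliated and oviduct epithelium. The Spearman correlation of the pair was 0.942. With its own group the first array had 0.948 on average and the second 0.880, so only the second was closer to the other array than to its group. Ciliated epithelium in both samples fits, with a lower median excess of 2.68 and at most 0.058 elsewhere. An exchange of the 2 labels is excluded, since over genes higher in subcutaneous fat the array labelled subcutaneous control dog 4 lies at 0.0928 and the other at 1.08, where 0 is the subcutaneous and 1 the gonadal level. RNA of gonadal dog 6 carried into the subcutaneous dog 4 sample could also give the pattern, since genes high in every gonadal array (13 probe sets, among them C2, PDE8B, PRR15, UPK1B and WIF1) reach 28.5% of the level of gonadal dog 6 there and genes special to that array (132 probe sets) 24.8%, a ratio of 1.15 (bootstrap 1.03 to 1.31). Carry-over and oviduct tissue taken with both samples remain open, and no biological explanation tied to feeding was tested.

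Skeletal muscle transcripts are high in subcutaneous control dogs 3 and 4 and in gonadal ad libitum dog 2, and lower in subcutaneous ad libitum dog 7 (median excess 0.96, 50% of the genes over 1 log2 unit). Muscle fibres in the sampled tissue fit, since at least 85% of 20 detected muscle genes lie more than 1 log2 unit above the other arrays of the depot in each of the 3 high arrays, with a lowest median excess of 5.65. Spill of muscle RNA from another sample may give the same values and was not tested apart, and no biological explanation tied to feeding was tested.

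The 506 subcutaneous calls for feeding could come from the grouping by chance, from muscle and oviduct RNA in 2 of the 4 control samples, from RNA length, or from feeding. Of 100 splits of the dogs 3, the real one included, gave as many calls, and the highest, 3756, sets dogs 2, 6, 7 and 8 against the rest, which moves ad libitum dog 5 to the control side and may point to a structure of the samples beyond the groups. Without the 4 arrays the median of the higher calls was 1.18 against 1.25 with all, and with the actin covariate 1.02, so neither accounts for the whole difference, though part may go with RNA length, while the median standard error grew from 0.268 to 0.322 and 0.290 and the calls ended at 5 and 1. These medians are over probe sets chosen on the difference with all arrays, which favours a kept difference. The GAPDH 3' minus 5' signal, 2.52 in subcutaneous control and 2.51 in ad libitum arrays, did not differ with feeding as the actin signal did. The array labelled subcutaneous ad libitum dog 5 lies at 0.157 between the control mean (0) and the mean of the other ad libitum arrays (1) over 2703 probe sets called without dog 5, where the other ad libitum arrays, each held out in turn from the choice of as many probe sets, lie at 0.789 to 1.30 and the control arrays at -0.0474 to 0.296, so a control sample under that label fits on this measure, as may a dog that responded little or a sample rich in immune cells (macrophage score 2.22). Single genes go both ways, since CCL19, ACSL1 and GPAM, given above, lie apart from the other ad libitum arrays on the control side, while others run as labelled, with LEP at 10.56 (controls at most 9.93), ELOVL6 at 5.90 (at most 4.65) and CDO1 at 10.71 (at least 13.35), though ELOVL6 and CDO1 were picked with this array in the group, so the label stays open.

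For feeding in gonadal fat and for the interaction the real count is 0, which every split reaches by construction (100 of 100 each), so the splits say nothing about chance there. The highest counts among the other splits were 577 and 7. The depot calls exceed every other regrouping, with 1 of 35 splits in control dogs (highest other 3) and 1 of 100 in ad libitum dogs (highest other 826). Most of these splits break the pairing of the depots within a dog. Among the splits that part the depots of every dog, 8 and 11, the highest other count was 0 in both. These are so few that the smallest share they can give is 1 of 8 and 1 of 11, so by themselves they cannot exclude chance.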

How the results depend on the processing

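The fits without 2, 4 or 5 arrays and with the actin covariate were chosen after the result was seen, and the other alternatives were written before the data were examined. Calls for feeding in subcutaneous fat, 506 in the fit reported, were 173 with no filter, 308 with quantile normalization again, 60 with only the arrays of the comparison, 179 at 1 probe set per gene (fewer probe sets tested) and 1712 at a threshold of 0.1. They were 325 without the 2 arrays, 5 without the 4 arrays, 3 without these and subcutaneous ad libitum dog 7 (fewer samples) and 1 with the actin covariate. Leaving out 1 dog gave 3 to 2703. Depot calls in control dogs, 627, were 275 with no filter, 412 with only their own arrays, 1346 with the dog as a random block, 270 at 1 probe set per gene, 1478 at 0.1, 341 without the 4 arrays, 200 without the 5 and 199 with the actin covariate, and 143 to 1050 leaving out 1 dog. Depot calls in ad libitum dogs, 1545, were 984 with only their own arrays, 2495 with the dog as a random block, 668 at 1 probe set per gene and 2739 at 0.1, and 497 to 1620 leaving out 1 dog. For the interaction 1 probe set passed without the 2 arrays and 0 to 5 leaving out 1 dog. The 0 calls for feeding in gonadal fat held in every alternative, and the other alternatives that were run moved none of the counts by more than 1.5 times. All 506, 627 and 1545 calls kept their sign without the 2, the 4 or the 5 arrays. These fits share most arrays with the fit that chose the calls, so a kept sign was likely from the start. Of 28 named genes called for feeding in subcutaneous fat all 28 missed the threshold in at least 1 fit that left out a dog, against 23 of 39 and 16 of 44 for the depots. Without the 4 arrays these numbers were 28, 15 and 7.

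Some signs changed, among named genes only for those that had not passed, and among lists called by camera only for skeletal muscle. Without the 4 arrays means of lists not called also turned, such as inflammation (0.11 to -0.26) and endothelium (0.07 to -0.28) for feeding in subcutaneous fat, fatty acid synthesis for depot in control dogs (0.36 to -0.04), and adipocyte identity (-0.17 to 0.07) and skeletal muscle (0.76 to -0.67) for depot in ad libitum dogs. The skeletal muscle mean for feeding in gonadal fat turned from 1.15 to -0.29. Without the 4 arrays MYLPF stood at 0.30 for feeding in subcutaneous fat and 0.060 for depot in control dogs, and MYH2 at 0.58 for feeding. The skeletal muscle list stood there at 0.41 for feeding, 0.031 for depot in control dogs and -0.70 for the interaction, where the arrays left out are those with the most muscle transcripts. With subcutaneous ad libitum dog 7 also left out it was -0.39 for the interaction and unchanged for depot in control dogs, and ADIPOQ in subcutaneous fat was -0.0084. CCL2 in subcutaneous fat ranged from -0.67 to 0.37 leaving out 1 dog. In gonadal fat ADIPOQ was -0.0077 with each array centred on its median and ranged from -0.21 to 0.28 leaving out 1 dog, and CCL2 was -0.0089 without the 2 arrays and ranged from -0.15 to 0.48. Apart from these and the changes shown by fewer probe sets or samples, the cause was not tested. With 47.2% to 49.0% of probe sets at or above the floor in an array, differences among dim genes such as TNF cannot be read. IL6 reached log2 8.61 but lay above the floor in only 2 arrays.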

Other observations

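The test of pairing and the list results here use lists and labels fixed before the data were examined, and the fit without the 4 arrays that carry most of the muscle or ciliated-cell transcripts was chosen after the result was seen. Lists called in no comparison by camera with all arrays were those of insulin signalling and glucose uptake (smallest adjusted p = 0.257), endothelium and angiogenesis (0.736), brown and beige fat (0.544), the circadian clock (0.525), the hypoxia response (0.443), sex steroid and glucocorticoid signalling (0.172) and the cell cycle (0.429). Without those 4 arrays the endothelium list was called by camera for feeding in subcutaneous fat (adjusted p = 0.0305) and in gonadal fat (0.00859), for depot in control dogs (0.0225) and for the interaction (8.02e-06). With an estimated correlation none of these held (0.894, 0.814, 0.797 and 0.78). Among the members of the lists not called, ANKRD37 fell with feeding in subcutaneous fat, and ENO1 (-0.68 ± 0.20, adjusted p = 0.0484) and PCNA (-0.41 ± 0.12, adjusted p = 0.048, and 0.0899 with the dog as a fixed block) were lower in gonadal fat of ad libitum dogs. Markers of T and NK cells (2 measured), B and plasma cells (3), neutrophils and blood (4), skin and mammary epithelium (2), ovary and reproductive tract (2) and nerve (3) had too few members for a test.

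Correlations across probe sets between the deviations of the 2 depots of a dog from their group means were 0.26, 0.53, 0.18, -0.05, 0.31, 0.01, 0.30, 0.35 and 0.08 for dogs 1 to 9. Genes are not independent replicates, so these are given as values with no test.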
